A study of Drosophila melanogaster with 4 samples.

How the data were processed

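Chromatin immunoprecipitation followed by sequencing was carried out on whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying. Per the labels, the flies carried a transgene for Gug fused to eGFP, and the fusion protein was precipitated with an antibody against GFP. Gug (Grunge, the fly Atrophin) is a nuclear co-repressor that works with nuclear receptors. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The labels give 4 biological replicates of 1 group, each with technical replicate 1, and the samples used here include no control sample.

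The deposited files are peak lists on the dm6 build. Per the README deposited with each sample, a thresholded list was made from that replicate's own alignment and further input files whose role is not stated, so peaks were called per replicate. A shared one of those inputs also enters the tracks of fold change over control. A longer ranked list was made per replicate. Series-level lists were made from the alignments of all 4 replicates, per the same README texts, which do not say which replicates were set against each other. The aligner, the peak caller and their versions are not given in the sources used here. Each list holds a signal score per peak, which is the authors' own value for that peak and was used only to describe, rank and filter peaks within a list. The deposited IDR score of each peak (IDR is the irreproducible discovery rate, a measure of rank agreement) was at least 830 in every thresholded list, which corresponds to an IDR of 0.0100 under the usual scaling. The deposited lists also give a -log10 q-value per peak, and the ranked lists a -log10 IDR. The files give no read counts, so the depth of each library is unknown and no interval that needs depth is given.

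Peaks on 2L, 2R, 3L, 3R, 4, X and Y were used. All of them lie within the chromosome lengths of the dm6 reference sequence. Summits of the 4 thresholded lists within 200 bp were joined, and a joined region with a peak in at least 2 lists was called reproducible. The position of a region is the median of its summits, and coordinates are 1-based. Overlap of 2 lists means at least 1 bp shared, and was set against 1000 circular shifts of 1 list within each chromosome (1-sided permutation test). Spearman correlations of signal were taken across shared peaks, which are not independent replicates, and carry no p-value.

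Transcription start sites (TSSs) and gene parts of 13968 protein-coding genes came from Ensembl release 115. Each summit was given to 1 class in the order 5' UTR, coding exon, 3' UTR, intron, intergenic. Shares were set against 1000 sets of random positions with the same number per chromosome (2-sided permutation test, smallest possible p 0.0020). A gene was called bound if a region summit lay within 1 kb of any of its TSSs. Bound members of 20 gene lists were compared with all other protein-coding genes by Fisher's exact test (2-sided) with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Of the list symbols 557 were matched, 8 of them through an older name in a mapping made after the data had been seen, and 1 (Cdx) was not matched. Peaks outside the main arms were left out of the comparisons. The p-values of gene lists and motifs describe genes and regions, which are not replicates.

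Matches to 18 motifs and all 2080 6-mers (reverse complements joined) were searched within 100 bp of region summits and in 1 flank window of equal width per region. Flank windows were centred 500 to 1500 bp from the same summit. The exact McNemar test was 2-sided, with Benjamini-Hochberg adjustment. A motif here is a short consensus, so a match does not show that its factor binds.

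The gene lists, motifs, main tests and the rule for named genes were fixed before the data were examined. By that rule the text names the 25 regions called in all 4 replicates with the highest mean percentile of signal, by the gene of the nearest TSS. It also names up to 4 bound and 2 unbound members of each list, Gug, every motif, and the 5 most enriched and 3 most depleted 6-mers. Genes outside the rule are said to be chosen after their values were seen. Alternatives covered the number of replicates required, the authors' series-level sets, stricter and equal-length lists, the joining distance, each replicate left out, the TSS window, the rule that assigns regions to genes, and the backgrounds. Added after the data had been seen were lists without peaks of a -log10 q below 1, overlap of the stronger 50% of each list, overlap without each replicate, and the list settings for the number of peaks and for rank agreement. Tests of explanations that were chosen after the result was seen are named as such where they are given.

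The steps were tested on simulated data. Simulated summits, partly placed within 500 bp of a TSS and partly random, returned a share of 60.1% within 1 kb of a TSS. The expected share was also 60.1%, but its random part was measured by the same step. The 2 values are thus equal by construction and do not test that step. Random summits alone did not differ from random positions in this share (permutation p = 0.990, 2-sided). A list of 14 genes bound at 57%, with others at 16%, was called in 64% of 200 simulated sets, and unraised lists were called in 0.263% of tests. A DREF sequence planted in 4% of flank windows was called and 0 other motifs were. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.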

Results

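The series profiled where a Gug-eGFP fusion protein sits on chromatin in whole embryos of 0 to 24 h, in 4 biological replicates of 1 group. Whole embryos mix all tissues and stages in that window. The 4 thresholded lists held 1948, 3786, 2117 and 2450 peaks on the main chromosome arms for replicates 1 to 4 (mean 2575 ± 834 SD, n = 4). Median peak width was 294.5 bp ± 9.15 (SD, n = 4). The depth of the libraries is unknown.

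How well the replicates matched was the first question the design allows. Ugalt, CG14100 and cbt led the regions found in all 4 lists, and the Ugalt region held the top signal in each of them. Across the 6 pairs of lists, 79.3% ± 8.05 (SD over pairs) of the shorter list's peaks overlapped the other list, from 70.0% for replicates 1 and 3 to 91.7% for replicates 2 and 3. Shifted lists overlapped by 1.17% on average and by at most 2.52%, so every pair gave the smallest p that 1000 shifts allow (0.0010, 1-sided permutation test). Shifting moves peaks off promoters, so this p does not separate shared sites from a shared location at promoters. Across shared peaks the signal ranks correlated with a Spearman rho between 0.650 and 0.826 (median 0.677, across peaks). Joining the lists gave 4466 regions, of which 1171 were found in all 4 replicates, 619 in 3, 853 in 2 and 1823 in 1. The 2643 regions found in at least 2 replicates are used from here on. Replicate 2 had 1239 peaks in no other thresholded list, against 131, 103 and 335 for replicates 1, 3 and 4.

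The 25 strongest regions found in all 4 replicates had mean signal percentiles of at least 98.7 within their lists. Of these, 19 lay within 1 kb of a TSS, 13 of them within 200 bp, and 0 lay in a coding exon. The first was the region 59 bp upstream of Ugalt, a UDP-galactose transporter gene (X, 2703699 to 2704083, intergenic, percentile 100 in every list). Next came regions 113 bp upstream of CG14100 (3L, 19590456 to 19590798, intergenic, percentile 99.96 ± 0.011 SD, n = 4) and 1413 bp upstream of cbt, which encodes the zinc-finger factor Cabut (2L, 480911 to 481273, in an intron, percentile 99.9 ± 0.043 SD, n = 4). The region upstream of cbt also lies within the span of the gene ush (2L, 476220 to 540560). Genes of DNA-binding and chromatin proteins among the 25 were HmgZ (2R, 21703086 to 21703675), Adf1 (2R, 6662875 to 6663251), Sox14 (2R, 23978380 to 23978702), the Polycomb-group gene ph-p (X, 2137195 to 2137528) and Chro, which encodes Chromator (3L, 22878729 to 22879064). Signalling genes were Shc, which encodes an adaptor of receptor tyrosine kinases (3L, 9426692 to 9427070, 110 bp upstream), the kinase gene Lk6 (3R, 11760902 to 11761184) and moody, a G protein-coupled receptor gene of the blood-brain barrier (X, 2050152 to 2050428). The region nearest to tara lay 3166 bp upstream of its TSS (3R, 16222329 to 16222651, intergenic). The other nearest genes were Tcs5, eIF6, CG1888, PNPase, CG7601, CG11050, CG32772, CG16753, CenG1A, px, tank, MFS10 and CG3726.

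At the gene of the tagged protein itself, all 4 replicates had peaks. Gug lies on 3L from 8449922 to 8472669 on the plus strand. A region 50 bp upstream of its TSS (8449673 to 8450162, intergenic) was found in all 4 lists at a low signal percentile (28.8 ± 22.3 SD, n = 4). Inside the gene, intronic regions at 8455369 to 8455876 (percentile 67.2 ± 4.54 SD, n = 4) and 8458204 to 8458474 (percentile 96.0 ± 2.17 SD, n = 4) were also in all 4 lists. Within 20 kb on either side lay regions near the TSSs of Unr (8442265 to 8442568, 4 replicates) and CG6983 (8448508 to 8449006, 2 replicates). The 5 regions of this window amount to 79.7 per Mb, against 19.2 per Mb over the arms. An inserted transgene can add copies of its own locus, and no list from a control library was used here.

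**Figure D1:**
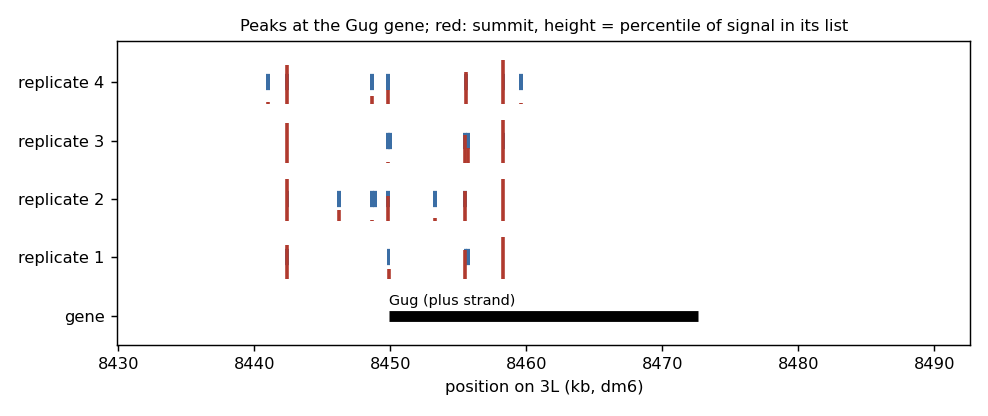
Peaks of the 4 replicate lists (blue bars, 1 row per replicate) around the Gug gene (black bar) along 3L in kb. Red lines mark summits, with the line's height giving the percentile of signal within the replicate's list; the intronic summit near position 8458319 reached a mean percentile of 96.0 over the 4 replicates.

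Gug-eGFP regions lay mostly at promoters and almost never in coding exons. Of the 2643 regions, 1634 (61.8%; Wilson 95% interval 59.96 to 63.7) had their summit within 1 kb of a TSS, 3.04 times the 20.4% of random positions (permutation p = 0.0020, 2-sided, the smallest possible). In the single lists this share was 61.4% ± 6.31 (SD, n = 4). Summits within 1 kb lay upstream of the nearest TSS in 81.3% of cases. The 5' UTR held 9.12% of summits (2.70 times random) and intergenic sequence 44.6% (1.37 times random), each with a permutation p = 0.0020. Coding exons held 12 regions, or 0.454% against 16.8% of random positions, and 3' UTRs 1.21% against 4.97% (permutation p = 0.0020 for each). Introns held 44.6% against 42.2% (permutation p = 0.0160), a difference that was not past the threshold for regions in all 4 replicates (permutation p = 0.228), without replicate 4 (p = 0.130), with the authors' conservative set (p = 0.511), with the stronger 50% of each list (p = 0.482) or with lists of equal length (p = 0.392). The promoter share rose with signal within the lists, from 55.3% ± 5.32 in the lowest quartile to 70.2% ± 6.78 in the highest (mean ± SD, n = 4), and the highest quartile exceeded the lowest in each of the 4 lists.

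**Figure D2:**
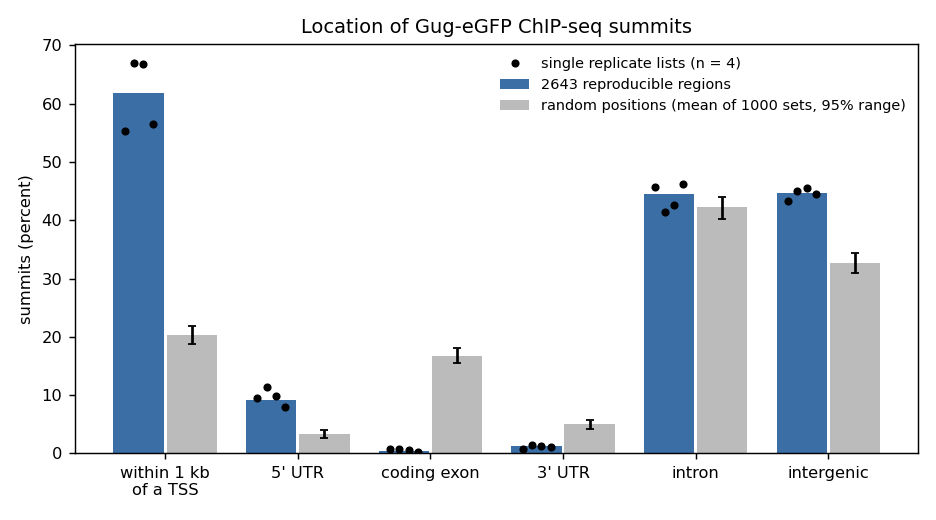
Share of summits in percent within 1 kb of a TSS and in each gene part, for the 2643 regions (blue bars), the 4 single replicate lists (points) and random positions (grey bars, mean of 1000 sets with the central 95%). The 61.8% of regions within 1 kb of a TSS stand above the 20.4% of random positions, and coding exons held 0.454% against 16.8%.

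Along the chromosomes, region density was highest on X and lowest on 4 and Y. It was 22.003 regions per Mb on X, 20.2 on 2L, 19.3 on 2R, 18.7 on 3L and 19.6 on 3R, and the spread over these arms was not tested. Chromosome 4 had 9 regions (6.68 per Mb) and Y had 1. The X to autosome ratio of peak density was 1.18 ± 0.105 (SD, n = 4) and exceeded 1 in all 4 replicates. Counted by genes, X and the large autosomes did not differ past the threshold, with 15.5% of X-linked genes and 16.02% of autosomal genes bound (Fisher's exact p = 0.546, 2-sided).

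By gene group, components of the EGFR pathway and cytosolic ribosomal protein genes were bound more often than other genes, and odorant and gustatory receptor genes less often. In all, 2216 protein-coding genes (15.9%) had a region within 1 kb of a TSS, and 2 of 20 lists had more bound members and 1 had fewer. In the EGFR pathway list 8 of 14 genes were bound (57.1%; single lists 42.9% ± 5.83 SD, n = 4; Fisher's exact test, adjusted p = 0.0032). They were the ligand genes spi (139 bp from a TSS, percentile 93.1 ± 2.61 SD, n = 4) and Krn, the GTPase gene Ras85D, the ETS factor genes pnt and aop, the inhibitor genes aos and sty, and edl. Of these, pnt, aos, sty and edl lie outside the rule for named genes and were named after their values were seen. The receptor gene Egfr and kek1 were unbound. The EGFR call was lost with regions in all 4 replicates (2 of 14, Fisher's exact adjusted p = 0.861), with the authors' conservative set (adjusted p = 0.0529), with the stronger 50% of each list (adjusted p = 0.459), with a 500 bp window (adjusted p = 0.193) and over gene bodies matched on length (permutation adjusted p = 0.190).

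Of the cytosolic ribosomal protein genes, 37 of 85 were bound (43.5%; single lists 37.4% ± 16.98 SD, n = 4; Fisher's exact test, adjusted p = 2.43e-08). RpL34b (percentile 94.3 ± 2.56 SD, n = 4), RpL32 (93.7 ± 3.14 SD, n = 4), RpS27 (81.6 ± 10.6 SD, n = 4) and RpS28b (81.2 ± 12.4 SD, n = 4) led the list, and RpL10 and RpL10Aa were unbound. Without replicate 2 the list had 24 bound members (Fisher's exact adjusted p = 8.25e-04), and without replicate 4 it had 26 (adjusted p = 0.0012). With regions in all 4 replicates 13 were bound, which was not past the threshold (Fisher's exact adjusted p = 0.225). Among mitochondrial ribosomal protein genes 16 of 73 were bound (21.9%; single lists 24.0% ± 12.7 SD, n = 4; Fisher's exact adjusted p = 0.334). These included mRpS23 and mRpL41, with mean percentiles of 99.1 ± 0.281 and 98.7 ± 0.850 (SD, n = 4), and mRpS10 and mRpL23. The mRpS23 region is the one nearest to CenG1A, and mRpL1 and mRpL10 were unbound. Against genes of like length and TSS number, the mitochondrial list had more bound members than drawn (6.64 expected, permutation adjusted p = 0.0067). With the nearest TSS only, 9 of the 73 were bound, 12.3% against 14.7% of all protein-coding genes (Fisher's exact adjusted p = 0.822). The list was also called with the authors' conservative set (Fisher's exact adjusted p = 0.0107), their largest set (0.0032) and a 2 kb window (0.0334). So it was over gene bodies matched on length (permutation adjusted p = 0.0013). In all, 5 alternatives called it, 15 did not, and 1 turned its direction.

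Odorant and gustatory receptor genes, which are expressed in sensory neurons, had 3 bound members of 119 (Or88a, Or9a and Gr32a; single lists 1.68% ± 0.686 SD, n = 4; Fisher's exact adjusted p = 3.63e-05), and Gr10a and Gr10b were among those unbound. Of 22 chorion and Jonah protease genes 0 were bound, Cp15 and Cp16 among the unbound (Fisher's exact adjusted p = 0.127, unadjusted p = 0.0380). Likewise 0 of 12 Hox genes and cofactors (abd-A and Abd-B among the unbound; adjusted p = 0.426, unadjusted p = 0.234) and 0 of 9 pair-rule genes (eve and ftz among the unbound; adjusted p = 0.571, unadjusted p = 0.371) had a region within 1 kb of a TSS (Fisher's exact test). With the nearest TSS only, 5 of the 12 Hox genes and cofactors were bound (41.7%, Fisher's exact adjusted p = 0.0444). The chorion and Jonah list passed the threshold, as fewer, with the authors' largest set (Fisher's exact adjusted p = 0.0151) and a 2 kb window (0.0449), but not in 19 alternatives.

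The other lists did not pass the threshold. Heat shock genes had 5 bound of 12 (adjusted p = 0.119), led by Hsp27 (percentile 97.47 ± 0.970 SD, n = 4; Fisher's exact test throughout) and Hsc70-4, with stv and Hsp83, and DnaJ-1 and Hsc70-3 unbound. The Fat, planar polarity and Hippo list had 7 of 19 (exact test, adjusted p = 0.109), with app, kibra, ds and mats bound and dachs and dgo unbound. The Notch list had 6 of 20 (adjusted p = 0.323): gro, which encodes the co-repressor Groucho (percentile 94.9 ± 1.14 SD, n = 4, exact test), numb, E(spl)mdelta-HLH and E(spl)m3-HLH led, and Delta and E(spl)m4-BFM were unbound. Nuclear receptor genes had 6 of 21 (exact test, adjusted p = 0.323), led by Hr96, ERR, usp and Hnf4, with dsf and EcR unbound. The dorsoventral and Dpp list had 6 of 28 (exact test, adjusted p = 0.620), led by Mad, cact, ush and brk, with Dad and dl unbound. Germline genes had 3 of 14 (orb, nanos and stau, exact test, adjusted p = 0.636; AGO3 and aub unbound), and gap and head gap genes 2 of 13 (bcd and cnc, adjusted p = 1; btd and cad unbound). The Notch list was called in 4 alternatives and not in 17. The 4 were the authors' largest set (Fisher's exact adjusted p = 0.0206), a 2 kb window (0.0334), the nearest TSS only (0.0444) and gene bodies matched on length (permutation adjusted p = 0.0320). The Fat, planar polarity and Hippo list was called with the largest set (Fisher's exact adjusted p = 0.0042) and the nearest TSS only (0.0121), but not in 19 alternatives.

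The lists for single tissues and for segment polarity did not pass the threshold. Among neural genes 2 of 23 were bound, elav (percentile 92.6 ± 2.79 SD, n = 4) and brat (91.7 ± 2.20 SD, n = 4), with ac and ase unbound. Muscle and mesoderm genes had 1 of 21 (tin, the heart factor Tinman, percentile 72.4 ± 5.48 SD, n = 4; Act57B and bap unbound). Only 1 member each was bound among segment polarity and Wnt/Hedgehog genes (nkd of 18; arm and ci unbound), gut and endoderm genes (bowl of 11; byn and drm unbound), tracheal genes (pyd of 12; bnl and btl unbound) and haemocyte genes (ush of 11; crq and eater unbound). Their adjusted p ranged from 0.426 to 1 (Fisher's exact test). With the nearest TSS only, 7 of the 18 segment polarity and Wnt/Hedgehog genes were bound (38.9%, Fisher's exact adjusted p = 0.0305).

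**Figure D3:**
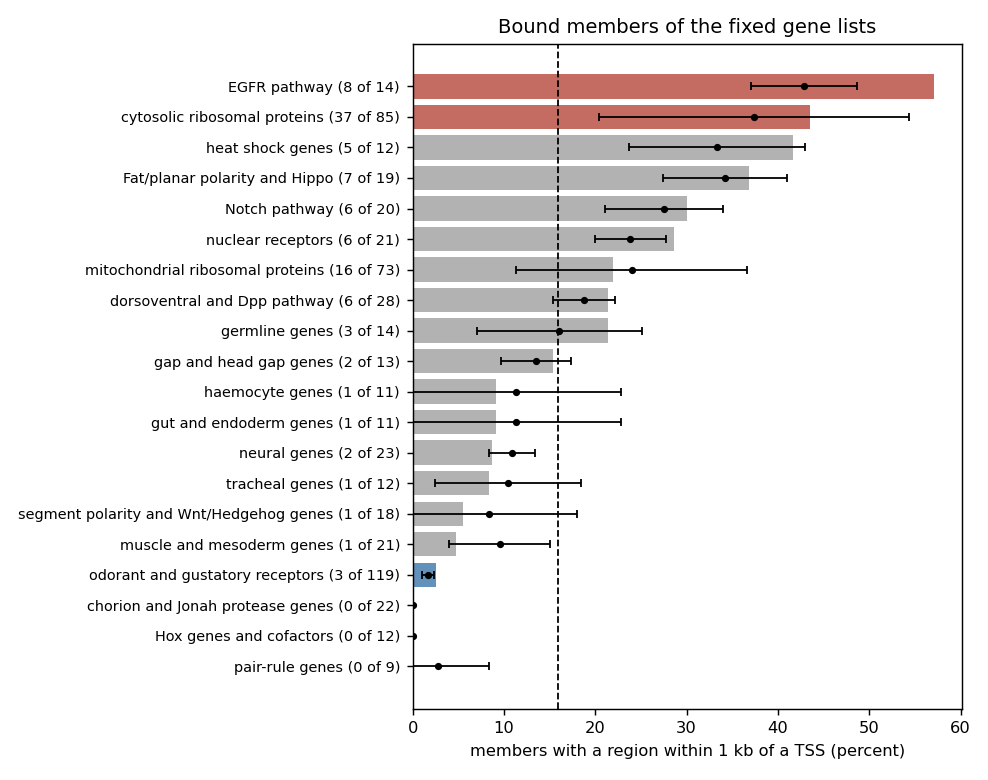
Share of members of each of 20 gene lists, in percent, with a region within 1 kb of a TSS (bars; red more and blue fewer than other genes past the adjusted threshold), with the mean and SD over the 4 single replicate lists (points and lines). The dashed line marks the 15.9% of all protein-coding genes; the EGFR pathway (57.1%) and cytosolic ribosomal proteins (43.5%) lie above it.

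Compared with their flanks, summits were AT-rich and carried more matches to core promoter motifs. Mean GC content was 38.2% within 100 bp of summits and 43.6% in flanks. The DREF motif TATCGATA, a core promoter element of housekeeping genes, was found at 4.05% of summits and 0.530% of flanks (7.64 times; exact McNemar adjusted p = 4.81e-18). The TATA box (14.7% against 7.79%, adjusted p = 6.44e-14), the homeodomain sequence TAATTA (14.2% against 10.6%, adjusted p = 3.13e-04) and the M1BP core promoter motif (1.97% against 0.946%, adjusted p = 0.0072) were also more frequent by the same exact test. In single lists DREF was found at 4.10% ± 1.98 of summits and the TATA box at 14.6% ± 1.15 (SD, n = 4). The homeodomain call was lost against random windows of the same GC content, where the ratio was 0.883 (exact test, adjusted p = 0.0978), with lists of equal length (adjusted p = 0.0510) and within 50 bp of summits (adjusted p = 0.108). The M1BP call was lost within 50 bp of summits (exact test, adjusted p = 0.870). Summits within 200 bp of a TSS were also set against TSSs of unbound genes at the same distance. There M1BP was at 4.40% and 3.84% (Fisher's exact adjusted p = 0.754), and no motif passed the threshold.

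Less frequent at summits were the motifs of Snail (0.716 times the flanks), Pleiohomeotic (0.864 times), Scalloped (0.685 times) and the CA repeat (0.692 times), with exact McNemar adjusted p of 0.0027, 0.0013, 3.13e-04 and 0.0139. The Pleiohomeotic and CA repeat calls were lost, and Snail's ratio was 1.15 (exact test, adjusted p = 0.261), against windows of the same GC content. With the stronger 50% of each list these 4 motifs did not pass the threshold (exact test, adjusted p from 0.0539 to 0.304). Without replicate 4, Snail (exact test, adjusted p = 0.0607), Scalloped (0.0734) and the CA repeat (0.0893) did not pass it, nor did Snail without replicate 2 (0.0736). Within 50 bp of summits Snail (exact test, adjusted p = 0.604), Pleiohomeotic (0.266) and Scalloped (0.449) did not pass it. Scalloped was also lost with regions in all 4 replicates (exact test, adjusted p = 0.347) and with summits joined within 100 bp (0.0695). The motifs of GAGA factor, Zelda, Twist, Suppressor of Hairless, Brinker, Stat92E, Ets (Pointed), Caudal, Grainy head and the Tailless site did not pass the threshold against flanks. GAGA factor matches, at 4.16% of summits and 3.71% of flanks (1.12 times), passed it in 4 of 19 alternatives. These were windows of the same GC content (2.04 times, exact test, adjusted p = 5.94e-05), windows of 200 bp either side (1.58 times), relaxed ranked peaks as control (1.45 times) and the authors' largest set (1.27 times). The Twist E-box was less frequent (0.813 times, exact McNemar adjusted p = 0.0511) and passed the threshold as such in 9 of 19 alternatives. Zelda, less frequent than in flanks (0.561 times), passed it in 4, but against windows of the same GC content its ratio was 1.64 (exact test, adjusted p = 0.243). The motif of Caudal, more frequent, passed it in 3; Brinker and the Tailless site passed it against some controls only, as did Caudal in the other direction. The Tailless site, a nuclear receptor sequence, was at 9.65% of summits and 9.57% of flanks (exact McNemar adjusted p = 1).

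In the open search, 436 6-mers were more frequent and 707 less frequent at summits. Against windows of the same GC content the counts were 267 and 271. The 5 leading ones by adjusted p were AAAATA, TTAAAA, ACAGTG, AAAAAT and AAATAT. ACAGTG stood out from these AT-only sequences, at 24.1% of summits and 8.63% of flanks (2.79 times; exact McNemar adjusted p = 3.04e-51). Of the less frequent ones, those with the lowest adjusted p were GGAGGA (2.80% against 11.2%), CTCCTC (3.25% against 10.9%) and CGAGGA (2.31% against 8.93%).

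**Figure D4:**
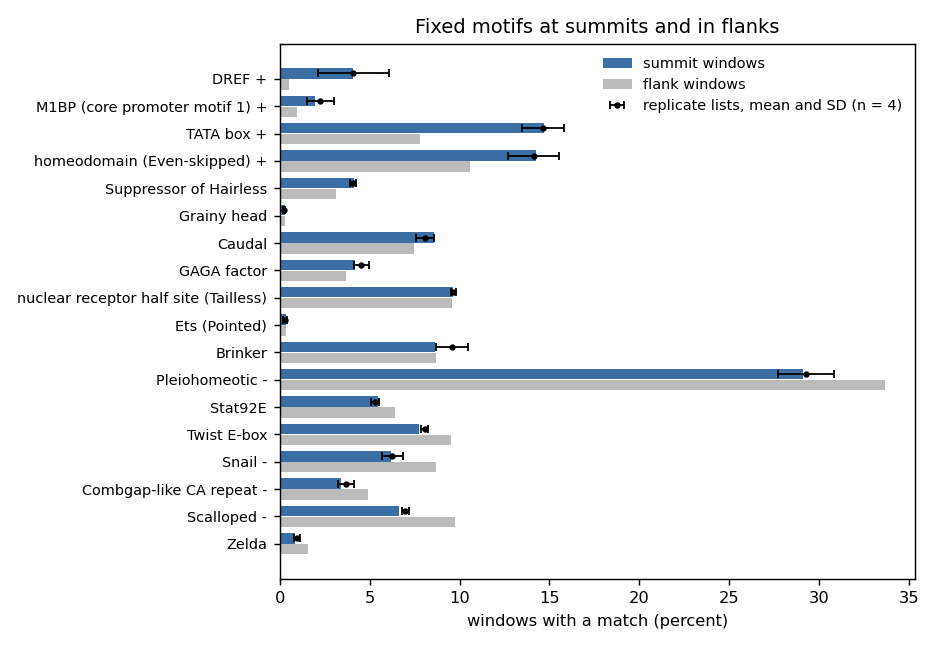
Share of windows in percent with a match to each of 18 motifs at the summits of 2643 regions (blue) and in flanks (grey), with the mean and SD over the 4 replicate lists (points and lines); plus and minus signs mark motifs past the adjusted threshold. DREF (4.05% against 0.530%) has the highest ratio.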

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

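All tests in this part that set a replicate against the others were fixed before the data were examined, and the test on the peaks found only in replicate 2 was chosen after its result was seen. In 54 sets of 4 replicate values, 5 had 1 replicate far from the other 3. For continuous values chance puts a replicate apart in about 1 in 20 sets, or 2.7 of 54. That rate does not hold for the sets on Y, gap genes and pair-rule genes. There 3 values are equal, so 1 differing peak or gene is enough.

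Within the thresholded lists, replicate 2 stood apart in its strongest peak, at Ugalt, with a signal of 1412 against 798.66 to 838.32 in the others. Ranked peaks of low IDR that are not in those lists reached higher signals of 2233, 2003, 1801 and 1401 in replicates 1 to 4, where replicate 2 was not the highest. Most of these ranked peaks lay on scaffolds outside the main arms (56 of 57, 32 of 37, 42 of 43 and 46 of 49 in replicates 1 to 4). Replicate 2 also stood apart in peaks on X, with 32.8 per Mb against 17.4 to 19.6, and on Y, with 0 against 0.273 per Mb in the others, which is 1 peak each. Its X to autosome ratio, 1.19, lay between those of the other replicates (1.08 to 1.32). Replicate 4 stood apart in the gap and head gap genes, with 7.69% bound against 15.4%, where bcd had a peak in 4 of 4 lists and cnc lacked one in replicate 4. Replicate 3 stood apart in the pair-rule genes, with 11.1% bound against 0% in the others, which is the single gene hry, named after its value was seen.

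Peaks of the thresholded lists on scaffolds outside the main arms, which the comparisons did not use, numbered 95, 55, 77 and 110 in replicates 1 to 4. Their highest signal was 476.08, 513.41, 375.56 and 382.78. No control list was used here to set them against.

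The 1239 peaks of replicate 2 that were in no other thresholded list form a pattern that the length of its list could produce. Of these, 97.3% overlapped a relaxed ranked peak of another replicate, against a mean of 42.7% and a highest value of 46.4% for shifted positions. Only 56.3% were in the relaxed lists of all 3 other replicates, and the unshared peaks of replicates 1, 3 and 4 overlapped a relaxed peak elsewhere in 95.1% to 98.2% of cases. Relaxed ranked peaks lay within 1 kb of a TSS of 12073 of 13968 genes, and shifting moves peaks off promoters. The shifted positions are thus a weak comparison, and the overlap alone does not show the same signal under the threshold. A relaxed peak in at least 1 other replicate is also not particular to replicate 2. What made its list longer stays open, since the depth is unknown. With 1 group, no biological explanation was tested.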

How the results depend on the processing

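The tests without peaks of a -log10 q below 1, the overlap of the stronger 50% of each list or without a replicate, and the alternatives for peak number and rank agreement were chosen after the data were seen. The share of regions within 1 kb of a TSS kept its direction and side of the threshold in every alternative tried, as did the overlap between lists (63.3% to 81.8%). Leaving out 1 replicate gave 1972 to 2397 regions, a TSS share of 60.4% to 65.0%, an X to autosome ratio of 1.14 to 1.18, 2 gene lists with more bound members, 4 enriched motifs, 368 to 432 6-mers, 4 to 5 regions at the Gug locus, 2172 to 2784 peaks per list, a median rho of 0.657 to 0.682 and an overlap of 74.2% to 81.8%. Requiring all 4 replicates gave 1171 regions, an X to autosome ratio of 1.27, 282 more and 439 less frequent 6-mers and 0 lists with more bound members (Fisher's exact test; 1 list at an unadjusted p under 0.05). The authors' largest set gave 4488 regions, 5 lists and 9 regions at the Gug locus. The stronger 50% of each list gave 1288 peaks per list, 1387 regions, 458 less frequent 6-mers, 1 list and 3 regions at the Gug locus; fewer peaks enter by construction. There was 1 list with a 500 bp window, 4 with 2 kb and 9 with the nearest TSS only, where segment polarity genes (38.9%, Fisher's exact adjusted p = 0.0305) and Hox genes (41.7%, adjusted p = 0.0444) turned from fewer to more. Within 50 bp of summits 2 motifs were enriched, and within 200 bp the CA repeat turned to a ratio of 1.12. Against windows of the same GC content 267 6-mers were more and 271 less frequent, and ratios turned direction for the Tailless site (0.810), the homeodomain (0.883), Snail (1.15), Brinker (1.44), Caudal (0.769) and Zelda (1.64, exact test, adjusted p = 0.243). Apart from list length and base composition, which these settings change by construction, the cause was not tested. Of the values for single lists, motifs, 6-mers and gene parts, 69 reversed in direction; in 8 the main or the alternative value passed the threshold, and in 61 neither did. Of the rest, 910 stayed on the same side of the threshold or, as counts, did not move. Without a change of direction, 37 passed the threshold only in the alternative and 29 lost it, and 8 counts moved. The 61 were as follows, lists as percent bound and motifs as ratios. Gap genes stayed at 15.4% while the share of all protein-coding genes changed, with at least 3 replicates, lists of equal length, each replicate left out and a 500 bp window. With the nearest TSS only, gap genes were at 30.8%, pair-rule genes at 33.3%, muscle genes at 28.6%, gut and haemocyte genes at 18.2%, tracheal genes at 25%, germline genes at 14.3% and mitochondrial ribosomal proteins at 12.3%. Germline genes were at 7.14% with at least 3 or all 4 replicates, at 7.14% to 21.4% with 1 replicate left out, and at 42.9% by gene body. Muscle genes were at 28.6% with the authors' largest set, 23.8% with 2 kb and 47.6% by gene body, and neural genes at 8.70% with all 4 replicates. With the authors' largest set haemocyte genes were at 27.3% (also with their conservative set), tracheal genes at 25% and dorsoventral genes at 21.4%; the last were at 7.14% with 500 bp and 21.4% with matched genes. Brinker was at 1.10 with all 4 replicates, 1.06 and 1.07 with the authors' conservative and largest sets, 1.00 (above 1) and 1.01 with summits joined within 100 and 500 bp, 0.916 to 1.04 with 1 replicate left out, and 1.17 and 1.08 within 50 and 200 bp. Stat92E was at 1.05 with all 4 replicates, 1.08 with the conservative set, 1.01 with summits joined within 100 bp, 0.894 to 1.12 with 1 replicate left out and 1.16 against relaxed peaks. The Tailless site was at 0.947 with the largest set, 0.971 with lists of equal length, 0.940 with summits joined within 100 bp, 0.988 without peaks of low q and 0.968 within 200 bp. Suppressor of Hairless was at 0.994 with the largest set, 0.965 and 0.920 with summits joined within 100 and 500 bp and 0.978 within 50 bp, and Caudal at 0.984 with the largest set. Grainy head was at 0.455 with lists of equal length, 0.875 with summits joined within 100 bp and 0.625 to 1.75 with 1 replicate left out. GAGA factor was at 0.932 with intervals joined, 0.979 to 1.16 with 1 replicate left out and 0.580 within 50 bp. Zelda was at 1.64 against windows of the same GC content. Depth is unknown, so it sets no stated limit.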

Other observations

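Tests chosen only after the result was seen are those on ribosomal protein genes, on base composition, on the TATA box apart from DREF, and on the unshared peaks of replicate 2. Several of them use alternatives planned before; the other tests were chosen before. Promoters shared by divergent genes were bound more often than single promoters. Of 1691 pairs of genes that start within 500 bp of each other in opposite directions, 443 (26.2%) had a region within 500 bp of the midpoint, against 790 of 10586 single promoters (7.46%). The ratio was 3.51 (Fisher's exact p = 8.63e-98, across promoters, 2-sided). The share was higher in pairs in 4 of 4 replicates (24.5% ± 9.28 against 7.25% ± 3.04, mean ± SD, n = 4). A pair holds the TSSs of both its genes, which can raise its share even if each is bound as often as a single promoter. Single promoters were counted at the outermost TSS of each gene, so regions at other TSSs were missed. The ratio and its p thus do not by themselves show a preference for divergent promoters.

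DREF and M1BP matches were more frequent at promoters than at other regions, and ACAGTG matches less frequent. DREF was found at 6.43% of regions within 1 kb of a TSS and 0.198% of those farther away, and M1BP at 3.06% and 0.198% (Fisher's exact adjusted p = 4.20e-19 and 3.78e-08). TATA box matches, at 15.6% and 13.3%, did not differ past the threshold (ratio 1.18, Fisher's exact adjusted p = 0.162). The GAGA factor motif was at 4.90% and 2.97% (Fisher's exact adjusted p = 0.0322). The hypothesis that ACAGTG goes with promoters was not borne out, since 21.5% of regions within 1 kb and 28.2% of those farther away had a match (ratio 0.763, Fisher's exact adjusted p = 3.39e-04). Genes with the most regions nearest to their TSSs, named after their values were seen, were CHES-1-like and tara (11 each), shn (8), and Hr4 and Raf (7 each).

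When regions went to the gene of the nearest TSS only, 7 more lists passed the threshold, among them nuclear receptors and the dorsoventral and Dpp list. Without replicates 1, 2, 3 and 4 in turn, 2, 3, 5 and 2 of these 7 lists were still called. This argues against peaks of 1 replicate as the source of all 7 calls. The remaining calls were lost in each case, so dependence on 1 replicate stays open for them. Large intervals around developmental genes are a candidate explanation. To test it, the 1009 regions over 1 kb from a TSS were placed at random in noncoding sequence, and the other regions stayed in place. Both kinds together reached 44.7 members on average (central 95% 38 to 51), against 52 observed (permutation p = 0.0420). That count lies just above the bound set beforehand against interval size, but the lists had been picked for being called, so the bound was wrong and the test was read as undecided after its result was seen. Singly, 0 of the 7 lists passed the threshold against random placements (permutation test), and no biological explanation was tested. Bound members rose from 1 to 7 for segment polarity, 0 to 5 for Hox, 6 to 11 for dorsoventral and Dpp, and 6 to 9 for nuclear receptor genes. They rose only from 6 to 7 for Notch and 7 to 8 for Fat and Hippo, and stayed at 5 for heat shock genes. In these last lists interval size has little gain to explain.

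More cytosolic ribosomal protein genes were bound than other genes. Summits belonging to a neighbour's TSS were argued against as the whole cause. With the nearest TSS only the list was still called (Fisher's exact adjusted p = 1.33e-04, against 2.43e-08 with the 1 kb window). The longer list of replicate 2 was likewise argued against as the whole cause. Without it 24 genes were bound in place of 37 (Fisher's exact adjusted p = 8.25e-04). General signal at active promoters stays open: against genes with a relaxed ranked peak the adjusted p was 9.40e-07, but that background leaves out few genes. The call was also lost when all 4 replicates were required (13 of 85, Fisher's exact adjusted p = 0.225), and no biological explanation was tested.

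GC content as the whole cause was argued against for the TATA box and DREF, though it goes with part of the excess. The windows were matched on GC content only. AAAATA, TTAAAA, AAAAAT and AAATAT also stayed more frequent against them, so an excess of some AT-only sequences was not removed. The TATA box is AT-only too, and its excess cannot be told apart from that one. Against windows of the same GC content the TATA box ratio was 1.32 (exact McNemar adjusted p = 3.63e-04), down from 1.89 against flanks, and that of DREF was 3.69 (adjusted p = 1.90e-10), down from 7.64. The homeodomain ratio fell to 0.883, in line with base composition. Distance from the TSS stays a candidate explanation near TSSs. There, bound against unbound TSSs at the same distance gave a ratio of 1.43 for DREF (Fisher's exact p = 0.0195, adjusted 0.341) and 1.13 for the TATA box (p = 0.254, adjusted 0.500). Both lie under the bound of 1.5 set before for the 2 motifs together and split after the result. Over 1 kb from a protein-coding TSS the TATA box was at 13.3% of summits and 8.03% of flanks (ratio 1.65, exact McNemar p = 2.62e-04). This argues against nearness to such a TSS as the whole cause. Those flanks were not matched for GC content, and AAAATA was at 50.2% of the same summits and 35.6% of their flanks. Base composition thus stays a candidate explanation for the TATA box excess there. With 1 group, no biological explanation was tested.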
